A study of Canis lupus familiaris with 6 samples.

How the data were processed

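Gene expression was measured on Affymetrix canine arrays in MDCKII, a line of Madin-Darby canine kidney epithelial cells that polarizes in culture. Per the labels' protocols, 3 samples came from cells grown as a flat monolayer on plastic (2D) and 3 from cells plated on a thin layer of Matrigel, a basement membrane extract, of 100 µl per 60 mm dish under medium with 2% Matrigel (3D). Total RNA was extracted with Trizol 36 h after plating, and biotin-labelled cRNA was made from 4 µg of it, per the labels' protocols. The labels call the replicates biological. Each array has 1 colour, and no scan date or hybridization batch was used here.

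The deposited table holds 1 log2 value per probe set and array. The submitters' processing notes name RMA, a method that corrects background, quantile normalizes and summarizes probes on the log2 scale, and limma; their versions and the probe set definition are not given in the sources used here. The values did not lie on a single scale. In the arrays of replicates 2 and 3 the medians over 42924 probe sets were 7.06 to 7.08, the minima were 3.39 to 3.44, and none of the values was below 0. In the replicate 1 arrays the medians were 5.42 in 2D and 5.26 in 3D, and 246 and 413 values were below 0. In these 2 columns 100.0% of the 1045 and 1746 values below 1 lay within 0.006 of log2 of a multiple of 0.1, against 4.40% of all 2-decimal values in that range. Across probe sets, Pearson's r was 0.983 to 0.997 among the arrays of replicates 2 and 3, 0.861 to 0.872 between them and the replicate 1 arrays, and 0.888 between the 2 replicate 1 arrays; probe sets are not independent replicates. How the replicate 1 columns were made is not given in the sources used here. No label states the log base, which rests on the processing notes and the range of the values.

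The design set before the data were examined was a limma comparison of all 6 arrays without a block. Because the columns do not share a scale, the test was instead run on the 4 arrays of replicates 2 and 3 (2 per group), and the 3D minus 2D difference of the replicate 1 pair is reported beside it as a single untested value on its own scale. The comparison of all 6 arrays is reported with the alternatives. This change was made after the scales had been seen. The gene lists, the rule for named genes, the thresholds and the other alternatives, except those the closing section names as chosen later, were set before the data were examined.

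Of 43035 probe sets, 111 control probe sets were left out. The platform annotation gave 1 gene symbol for 29254 probe sets and several for 439, from which none was named, while 13231 are unnamed here. The Entrez identifiers of 27680 probe sets were found in the gene table of the canine assembly UU_Cfam_GSD_1.0, used for names only, and 0 symbols needed an update. The probe sets with 1 symbol stood for 15115 genes, of which 8254 had 2 or more probe sets. A gene was represented by its probe set with the highest mean over all 6 arrays, a choice blind to the difference between groups. No genome build is named in the sources used here, so no positions are given.

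Differences were tested on the log2 scale with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 42924 probe sets and a threshold of 0.05. There was no filter on level, since the table carries no detection calls. Standard errors are those of the limma estimate. Gene lists with at least 5 measured members (36 lists) were tested on gene-level values with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance in 1 direction. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom, and with a preset one to the number of genes. A call can then be lost without any correlation between members. Each list also has its members counted past the threshold over all probe sets and adjusted over the list alone. For replicate 1, a list's median difference was placed among 10000 random lists of the same size matched on mean level. Of the 36 lists, 14 lay among the 250 lowest or highest of theirs in replicate 1, and 10 of these were not called by camera. A small count in replicate 1 is therefore weak evidence for a shift of that list alone. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for joins and plots.

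The named genes were those of the Rab27-Slp and Rab3 list that passed, with SYTL2, SYTL4, RAB27A and RAB27B in any case, the 12 highest and 12 lowest log2 fold changes among genes that passed, leaving out symbols beginning with LOC, and up to 4 members per list with the smallest adjusted p. For a cell type or reference list with 0 changed members the member with the highest mean over all 6 arrays was taken, which mixes the scales. For the 12 highest and 12 lowest alone, the rule asked for groups of 3 values without overlap; as the scales differ, this became no overlap between the arrays of replicates 2 and 3 and the same sign in replicate 1. CCN2, PTPN14, LATS2, AJUBA, NUAK2, CRIM1, FN1, PODXL and the genes of the closing observations were named after their values were seen. SYTL4 was not analysed here.

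The number of arrays limits the precision. The median SD between the 2 arrays of a group was 0.0707 in 2D and 0.0990 in 3D. Across probe sets the 3D minus 2D difference had an SD of 1.25 in replicate 1, against 0.414 in replicate 2 and 0.343 in replicate 3. A single gene's replicate 1 difference within that spread says little on its own. The procedure was tested on simulated data of the same size: with 200 changed probe sets, 1.49% of those changed by 0.5 on the log2 scale were recovered, 41.8% of those changed by 1 and 97.0% of those changed by 2, with 9 calls among 42724 unchanged probe sets. With 2837 probe sets changed by 1, 93.8% were recovered and 4.45% of the calls were unchanged probe sets. That case is easier than the real data, where 755 of the 2837 called probe sets changed by at least 2-fold. Simulated with the spread of all 6 arrays and no block, 0 of the probe sets changed by 0.5, 1 or 2 were recovered. With the scale as a block, 24.2% of those changed by 2 were recovered, and 0 of those changed by 0.5 or 1. Alternatives were quantile normalization, median centring and cyclic loess on the deposited values, a filter on dim probe sets (median of the mean log2 values 6.33, 21465 probe sets left), eBayes with trend and robust, array weights, the replicate number as a block, the mean of a gene's probe sets, leaving out each array, a threshold of 0.01, limma's treat against a 1.2-fold change, and fits of all 6 arrays.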

Results

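Transcript levels were compared between MDCKII cells grown as a flat polarized monolayer (2D, 3 arrays) and MDCKII cells forming cysts on Matrigel (3D, 3 arrays), all 36 h after plating. The question behind the design was which genes are raised when the cells build cysts, as possible regulators of lumen formation. The 2 replicate 1 arrays carry values on another scale than the other 4 arrays, so that tests used replicates 2 and 3 (n = 2 arrays per group) and replicate 1 gives a separate, untested difference.

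**Figure D1:**
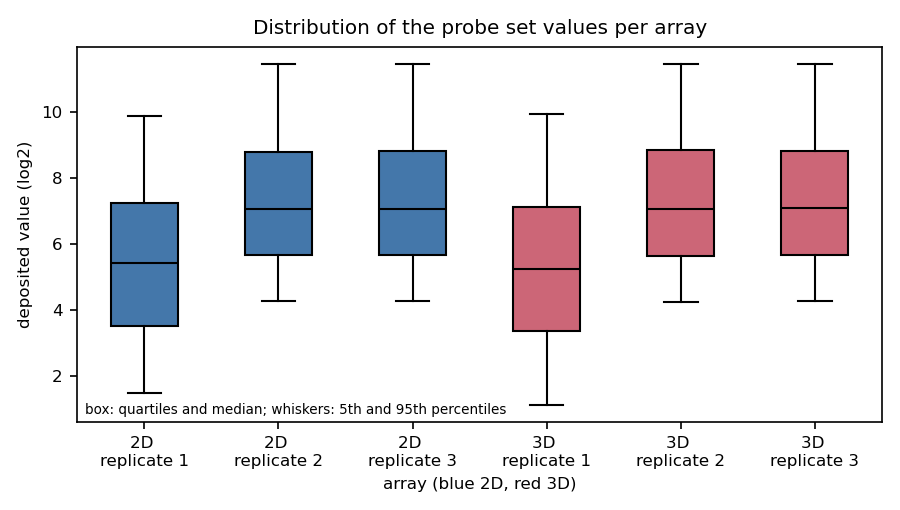
Distribution of the deposited log2 values of all tested probe sets on each array (vertical axis, log2 units), blue for 2D and red for 3D; boxes span the quartiles with the median as a line, and whiskers reach the 5th and 95th percentiles. The replicate 1 arrays have medians of 5.42 in 2D and 5.26 in 3D, while the other 4 arrays lie between 7.06 and 7.08.

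Cells in 3D had far more transcript of RIPPLY1, a transcriptional corepressor known from somite segmentation, and far less of ANKRD1, an ankyrin-repeat protein widely used as a readout of the coactivator YAP. RIPPLY1 was 35.6-fold higher in 3D, with a log2 fold change of 5.16 (SE 0.204, n = 2 arrays per group, limma adjusted p = 0.00145). ANKRD1 was lower, with a log2 fold change of -4.78 (SE 0.198, n = 2 arrays per group, limma adjusted p = 0.00145), and -3.09 on its second probe set. Its mean 3D level of 5.09 lay below the arrays' lower quartiles (5.64 to 5.67), so the size of the fall is uncertain. The replicate 1 differences were 5.44 for RIPPLY1, and -2.19 and -0.82 for the 2 probe sets of ANKRD1. Other genes that rose included FABP1, the liver fatty acid-binding protein (log2 fold change 3.99, SE 0.253), TXNIP, a thioredoxin-binding protein that restrains glucose uptake (3.97, SE 0.314), and PDZK1, a scaffold of the proximal tubule brush border (3.78, SE 0.154).

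PPP1R1B, an inhibitor of protein phosphatase 1, rose 14.0-fold on 1 of its 4 probe sets. RBP4, the plasma carrier of retinol, rose 7.94-fold, and RLBP1, which binds retinaldehyde, rose 5.92-fold, with a smaller rise on its second probe set. The tetraspanin TSPAN1 rose 6.57-fold, APOBEC1, the enzyme that edits apolipoprotein B mRNA, 5.98-fold, and SFTPD, the surfactant collectin, 4.99-fold. CAPN13, a calpain (log2 fold change 3.14), and TEX26 (2.68) rose from mean 2D levels of 5.41 and 4.69, below the arrays' lower quartiles, so the size of these rises is uncertain as well. The limma adjusted p of these 8 genes ranged from 0.00145 for APOBEC1 to 0.0125 for SFTPD. The rule that chose the 12 highest and 12 lowest genes required the same sign in replicate 1.

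Falls of at least 3.53-fold were seen for the other 11 of the 12 genes with the lowest log2 fold changes. CSF2, a myeloid growth factor, was 6.15-fold lower, the vasoconstrictor peptide precursor EDN1 5.13-fold, TGFB2 4.89-fold, the activin-binding protein FST 4.72-fold and LOX, which crosslinks collagen, 4.55-fold. IGSF23 was 4.35-fold lower, the metalloproteinase inhibitor TIMP3 4.20-fold, the kinase STK17A 4.10-fold, the activin subunit INHBA 3.90-fold, F3, which encodes tissue factor, 3.62-fold and the ectonucleotidase ENTPD3 3.53-fold. Their limma adjusted p ranged from 0.00343 for INHBA to 0.0354 for IGSF23. In replicate 1 LOX differed by -4.86 and INHBA by -0.42. The LOX value on 3D replicate 1 was 2.87, below that array's lower quartile of 3.38, so the size of its difference is uncertain.

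**Figure D2:**
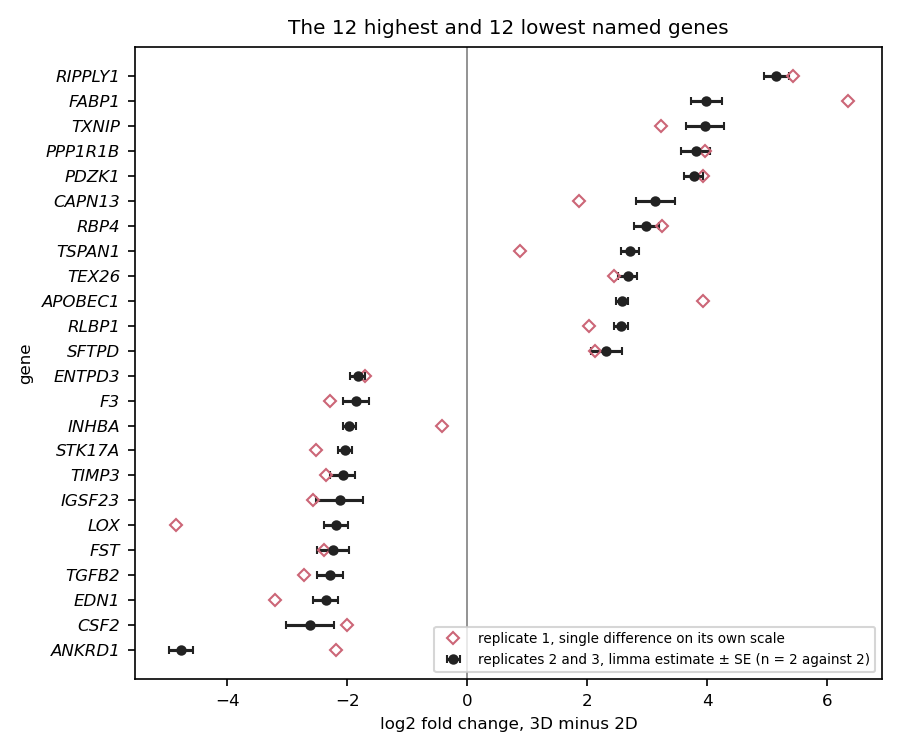
The 12 highest and 12 lowest named genes (vertical axis) with their log2 fold change, 3D minus 2D (horizontal axis, log2 units). Black points are limma estimates from replicates 2 and 3 with bars of 1 SE (n = 2 arrays per group), and open red diamonds are single replicate 1 differences on their own scale, whose sign was part of the rule that chose the genes; estimates run from RIPPLY1 at 5.16 to ANKRD1 at -4.78.

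Across the arrays of replicates 2 and 3, 2837 of 42924 probe sets differed at a limma adjusted p under 0.05, 1565 higher and 1272 lower in 3D. Among named genes 1102 differed, 635 higher and 467 lower, and 298 of them by at least 2-fold, 212 higher and 86 lower. The excess of higher genes among all calls did not hold for the mean of a gene's probe sets, with 565 higher and 588 lower. Among the 217 genes of at least 2-fold by that mean an excess did hold, with 140 higher and 77 lower. In replicate 1, 879 of the 1102 genes had the same sign (79.8%, against 48.7% if the signs were unrelated), as did 272 of the 298 genes with at least a 2-fold difference (91.3%, against 47.0%). The median replicate 1 difference of all genes was -0.11. With all 6 arrays in 1 limma fit without a block, as first planned, 0 probe sets passed and 105 had an unadjusted p under 0.05, and leaving out any 1 of the 4 arrays (2D replicate 2, 2D replicate 3, 3D replicate 2 or 3D replicate 3) also left 0, with 4683 to 10892 at an unadjusted p under 0.05. The poly-A spike-in controls were brighter on 3D replicates 1 and 2 than on the 2D arrays of the same scale, by 0.83 and 0.99 on the log2 scale, and of 4 actin and GAPDH control pairs, 2 had a larger 3' minus 5' difference on both 3D arrays of replicates 2 and 3 than on both 2D arrays.

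Target genes of YAP and TAZ, the coactivators restrained by the Hippo pathway, fell as a group. Of 21 measured members, 10 were lower in 3D, 0 were higher and 11 did not pass, with a median log2 fold change of -0.555 (limma camera adjusted p = 4.41e-06). The call did not hold with an estimated correlation (adjusted p = 0.751 with an estimated correlation), and held with fry (adjusted p = 0.0377). Beside ANKRD1, TGFB2 and F3, the matricellular genes CCN1 (-1.73, SE 0.105) and CCN2 (-1.57) fell, as did the Hippo pathway members LATS2 (-0.93), AJUBA (-0.99) and PTPN14 (-1.21), along with NUAK2 (-0.93) and CRIM1 (-0.56, with a limma adjusted p = 0.0506 under trend and robust priors). Adjusted over the list alone, 12 members were lower. All 10 members that fell were also lower in 3D in replicate 1, where the list's median difference was -2.07 and 0 of 10000 random lists had a median as low. In replicate 1 this was so for 3 lists, of which the basement membrane and the growth factor receptor and ligand lists were not called on replicates 2 and 3.

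Several lists on matrix and signalling did not shift as a whole but held members that changed in both directions. In the TGF-beta and BMP list, 5 of 24 members were lower, among them TGFB2, FST and BMP4 (-1.77, SE 0.107), and 1 was higher, the coreceptor gene TGFBR3 (0.76); adjusted over the list alone the counts were 6 and 2 (limma camera adjusted p = 0.0818, and 0.0444 with the mean of a gene's probe sets). In the EMT and mesenchymal list, 5 of 22 fell, including LOX, INHBA and the collagen gene COL5A2 (-0.83), while 2 rose, S100A4 (1.95, SE 0.124), a calcium-binding protein, and FN1 (0.84, but -0.81 in replicate 1); adjusted over the list alone 6 fell and 2 rose (limma camera adjusted p = 0.248). FN1 rose on 1 of its 4 probe sets and did not pass as their mean (0.16, limma adjusted p = 0.387). Of 24 actin, myosin and stress fibre genes, 3 fell, ACTN1 (-0.77), TPM1 (-0.59) and TAGLN2 (-0.49, but 0.35 in replicate 1). LIMA1 rose (0.72, but 0.06 in replicate 1). Adjusted over the list alone 5 fell and 1 rose (limma camera adjusted p = 0.643). TIMP3 fell and TIMP2 rose (0.70, but -0.14 in replicate 1) among 21 matrix proteases and inhibitors, with the same counts adjusted over the list alone. Of 27 integrin and focal adhesion genes ITGB5 rose 2.0-fold on 1 of its 5 probe sets and ITGB6 fell 2.51-fold, with 1 higher and 3 lower adjusted over the list alone. A second of the 5 ITGB6 probe sets passed, at -1.01. As the mean of their probe sets neither gene passed (ITGB5 0.52, limma adjusted p = 0.0615, and ITGB6 -0.46, limma adjusted p = 0.0772).

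The basement membrane list did not shift on replicates 2 and 3, with a median of -0.0275 (limma camera adjusted p = 0.684). On these arrays LAMC1 (0.94, SE 0.131), a laminin chain, and DAG1 (0.72), which encodes dystroglycan, were higher, though DAG1 did not pass as the mean of its probe sets (limma adjusted p = 0.0752). Here 20 of 22 members did not pass and 3 were higher adjusted over the list alone. In replicate 1 LAMC1 differed by -1.41 and DAG1 by -1.28, and the list's median difference was -1.11, with 0 of 10000 random lists as low; the difference between the replicates was not tested.

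Genes of the primary cilium, the sensory projection that epithelial cells carry on the apical side, rose as a group. Of 27 measured members 7 were higher in 3D, 0 were lower and 20 did not pass, and 12 were higher adjusted over the list alone. The intraflagellar transport genes IFT172 (1.39, SE 0.231), IFT140 (1.03, SE 0.157) and IFT52 (0.67) and the BBSome gene BBS9 (0.71) led the list. Its median was 0.24 (limma camera adjusted p = 0.00974), against an adjusted p = 0.751 with an estimated correlation, an adjusted p = 0.107 with fry and an adjusted p = 0.311 without 3D replicate 3. In replicate 1 the median difference was 0.56, 6 of the 7 members had the same sign, the exception being IFT140 (-0.06), and 2 of 10000 random lists had a median as high.

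The apical membrane and microvilli list had 4 of 28 members higher and 1 lower, and 8 and 2 adjusted over the list alone. GGT1, the brush border enzyme gamma-glutamyltransferase, rose 4.07-fold, the taurine transporter gene SLC6A6 rose 2.23-fold on 1 of its 3 probe sets (-0.47 in replicate 1), the sialomucin gene CD164 rose 1.58-fold, and RDX, which encodes radixin, fell 1.75-fold. CD164 did not pass as the mean of its probe sets (limma adjusted p = 0.0831). The median was 0.095 (limma camera adjusted p = 0.0445, and adjusted p = 0.751 with an estimated correlation). The direction was not shared by replicate 1, where the median difference was -0.445 (300 of 10000 random lists as low), and the median was below 0 in the fits of all 6 arrays on each scaling (-0.06 without a block, -0.05 quantile normalized, -0.01 median centred and -0.05 with cyclic loess). The call was also lost without 2D replicate 2 (adjusted p = 0.0632), without 2D replicate 3 (0.116) and without 3D replicate 3 (0.0800). It was lost without dim probe sets (adjusted p = 0.111), with the replicate block (0.0834), with the mean of a gene's probe sets (0.0623) and with fry (0.107). PODXL, which encodes the apical sialomucin podocalyxin, did not pass, at -0.01 on replicates 2 and 3 and -4.60 in replicate 1.

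Ion and water transport genes changed in both directions, 3 of 26 higher and 3 lower, and 4 and 3 adjusted over the list alone (limma camera adjusted p = 0.684). FXYD2, the gamma subunit of the sodium pump, rose 4.92-fold, carbonic anhydrase CA4 2.54-fold and the water channel AQP5 2.46-fold, whereas the bicarbonate cotransporter gene SLC4A7 fell 2.40-fold. Of 25 tight junction genes, CLDN2, which encodes a claudin that forms cation pores, rose 3.49-fold and 24 did not pass, with 2 higher and 2 lower adjusted over the list alone. Among 24 adherens junction and desmosome genes, CTNNB1, which encodes beta-catenin, rose 1.62-fold and PERP 1.56-fold, and the desmoglein DSG3 fell 3.51-fold, with 5 higher and 4 lower adjusted over the list alone. PERP did not pass as the mean of its probe sets (limma adjusted p = 0.0620). None of 14 keratin and epithelial cytoskeleton genes passed, either over all probe sets or adjusted over the list alone.

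For the polarity complexes and the vesicle machinery, few members passed. Of 26 polarity genes PARD3 was higher (0.65, SE 0.116) on 1 of its 4 probe sets, with a replicate 1 difference of -1.20, and did not pass as their mean (limma adjusted p = 0.267). PRKCI, the atypical protein kinase C, was lower (-0.56, SE 0.111, replicate 1 -0.66, limma adjusted p = 0.0561 under trend and robust priors). Adjusted over the list alone 2 were higher and 1 lower. In the Rab27-Slp and Rab3 list, 2 of 17 members rose, with 2 higher adjusted over the list alone. RPH3AL rose (0.88, SE 0.171, limma adjusted p = 0.0401) on 1 of its 2 probe sets (limma adjusted p = 0.0726 as their mean). In replicate 1 it differed by 0.06, and by -1.01 on its other probe set. RAB3D rose (0.61, SE 0.124, limma adjusted p = 0.0450, 0.0515 with median centring and 0.0571 under trend and robust priors), with a replicate 1 difference of 0.36. SYTL2, the synaptotagmin-like effector of Rab27, did not pass at 0.51 (SE 0.179, limma adjusted p = 0.157), was 1.59 higher in 3D in replicate 1, and had a second probe set at -0.34. RAB27A (-0.41, SE 0.121, limma adjusted p = 0.110) and RAB27B (0.00, SE 0.116, limma adjusted p = 1) did not pass either. None of 29 apical exocytosis and recycling endosome genes passed, also adjusted over the list alone.

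Genes of the unfolded protein and amino acid response fell as a group, with 4 of 25 lower, 0 higher and 10 lower adjusted over the list alone. They were HERPUD1 (-1.03, SE 0.0968), the chaperone genes HSPA5 (-0.74, SE 0.110) and HSP90B1 (-0.68), and DDIT4 (-0.66). The median was -0.37 (limma camera adjusted p = 2.77e-05, adjusted p = 0.751 with an estimated correlation and 0.107 with fry), and -0.58 in replicate 1, where all 4 had the same sign and 2 of 10000 random lists were as low. Interferon response genes had a median of -0.495 (limma camera adjusted p = 0.00513, and adjusted p = 0.847 with an estimated correlation), with ISG15 (-1.09) and USP18 (-0.92) lower, 17 of 19 not passing and 7 lower adjusted over the list alone; the call was lost without 3D replicate 3 (adjusted p = 0.116) and with fry (0.229). Replicate 1 gave a median difference of -0.43 for this list, with 555 of 10000 random lists as low. Inflammatory genes went both ways, with 3 of 29 higher and 2 lower, and 3 and 4 adjusted over the list alone. The chemokine gene CCL2 (1.84) and the acute-phase gene SAA1 (1.60) were among those that rose, and CSF2 and ICAM1 (-0.73) fell. SAA1 rose from a mean 2D level of 5.555, below the arrays' lower quartiles (5.64 to 5.67), so the size of its rise is uncertain. It differed by 2.22 in replicate 1, while another passing SAA1 probe set (1.505) differed by -0.38 there.

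Of 22 immediate early and ERK feedback genes, MYC (-1.17, SE 0.119), PHLDA1 (-1.05) and IER3 (-0.67) fell. The phosphatase gene DUSP1 rose (0.98, but 0.05 in replicate 1), and the counts adjusted over the list alone were the same. In the growth factor receptor and ligand list, 4 of 25 members fell, including VEGFA (-1.52, SE 0.169) and ERRFI1 (-0.83), which encodes neither a receptor nor a ligand. The 2 that rose were ERBB3 (1.38, but -0.68 in replicate 1) and EGF (1.04). Adjusted over the list alone 5 fell and 2 rose. This list's median was -0.02 (limma camera adjusted p = 0.684), against a replicate 1 median difference of -1.05, with 0 of 10000 random lists as low. WNT7A (-0.91) was the only member of 29 in the Wnt and Notch list to pass over all probe sets or adjusted over the list alone. The G2/M list had a median of -0.195 (limma camera adjusted p = 0.0378, and adjusted p = 0.751 with an estimated correlation) with 1 of 25 lower, ANLN (-0.85), which encodes anillin, also 1 adjusted over the list alone, and a replicate 1 median of 0.05 (4020 of 10000 random lists as high). The G1/S list had a median of -0.16 (limma camera adjusted p = 0.0445, and adjusted p = 0.751 with an estimated correlation) with 1 of 27 lower, the replication licensing gene CDC6 (-0.85), 2 adjusted over the list alone, and a replicate 1 median of -0.50 (8 of 10000 random lists as low). Both calls were lost without 3D replicate 2 (adjusted p = 0.0729 for G2/M and 0.115 for G1/S) and without 3D replicate 3 (0.0800 for each), the G2/M call also without 2D replicate 2 (0.106) and the G1/S call without 2D replicate 3 (0.106). Without dim probe sets neither was called (adjusted p = 0.0744 for G2/M, and higher for G1/S), nor was either with fry (0.107 for each), and G1/S was lost with cyclic loess (0.0544). DDB2 (0.61, but -0.39 in replicate 1, and 0.83 with 2.16 in replicate 1 on a second probe set) was the only one of 21 p53 target and apoptosis genes past the threshold, and it was the only rise adjusted over the list alone, beside 2 falls.

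Metabolic lists did not shift as a whole. Of 29 glycolysis and hypoxia genes 3 fell, the glucose transporter gene SLC2A1 (-0.98, SE 0.107), PFKFB3 (-0.86) and P4HA2 (-0.62), and 2 rose, including the aldolase gene ALDOC (1.13); adjusted over the list alone 8 fell and 6 rose (limma camera adjusted p = 0.712). PFKFB3 did not pass as the mean of its probe sets (limma adjusted p = 0.0598). In cholesterol synthesis MVD was lower (-0.89, but 0.61 higher in replicate 1), and 18 of 19 did not pass. In oxidative phosphorylation SDHC was higher (0.55) and 20 of 21 did not pass. For these 2 lists the counts adjusted over the list alone were also 1.

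**Figure D3:**
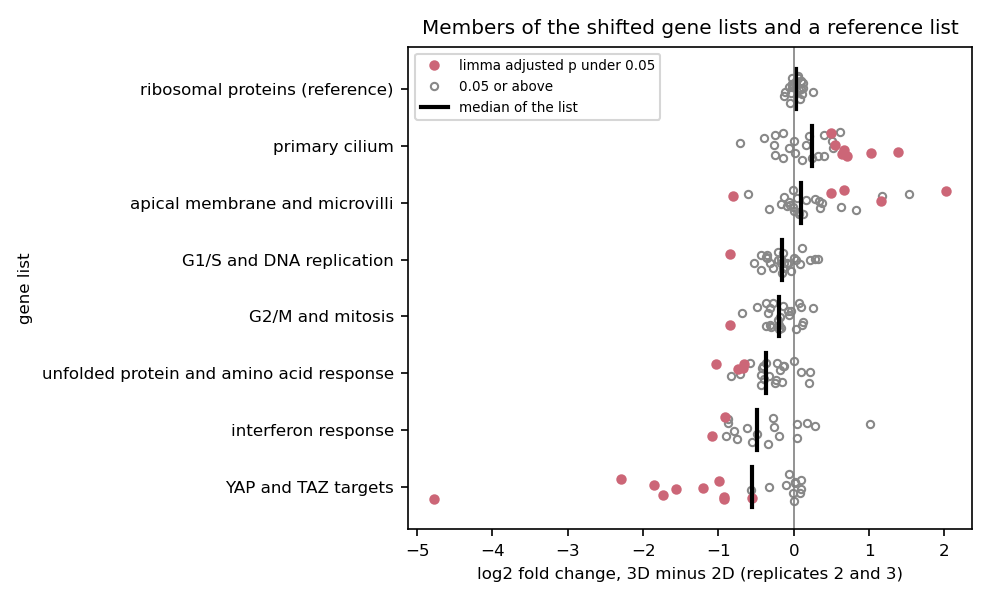
Log2 fold change, 3D minus 2D, from replicates 2 and 3 (horizontal axis, log2 units) of each measured member of the 7 lists called by limma's camera and of the ribosomal proteins. Filled red points passed a limma adjusted p of 0.05 over all probe sets, open grey points did not, and black bars mark medians, from -0.555 for YAP and TAZ targets to 0.24 for the primary cilium and 0.03 for the ribosomal proteins.

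Markers of kidney segments and of other cell types mostly did not pass. Of 15 proximal tubule markers, PDZK1 and the gluconeogenic enzyme gene FBP1 (1.38, SE 0.148) rose and 3 were higher adjusted over the list alone, with a median of 0.00. EGF was the only one of 13 loop of Henle and distal tubule markers past the threshold, also adjusted over the list alone, and the receptor gene FLT1 (-1.27, SE 0.136) the only one of 13 endothelial markers, also adjusted over the list alone. None of 11 collecting duct principal cell markers, 13 intercalated cell markers, 12 fibroblast markers, 15 leukocyte markers or 23 ribosomal proteins passed, nor did any adjusted over the list alone. The median, the mean and the camera direction differed in sign for 8 lists, of which 0 were called: polarity complexes, adherens junction, basement membrane, matrix proteases, immediate early, Wnt and Notch, collecting duct and intercalated cells. BBS9, EGF, ANLN, PTPN14, IFT140, IFT52, DUSP1, PERP, SDHC and DAG1 passed on 1 of their 2 or more probe sets. For the 5 lists without a change the rule named GATA3 (0.02), CA2 (0.01), COL3A1 (0.01), CD74 (0.29) and RPL9 (-0.06).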

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

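Both tests of the spike-in controls were chosen after the result was seen. The arrays carry control probe sets that are no part of the comparison, and their poly-A spike-in transcripts, which are usually added to the sample RNA before labelling, were brighter in 3D than in 2D on 2 of the 3 3D arrays, each set against the 2D arrays of the same scale. The mean difference over 36 probe sets was 0.828 on the log2 scale in replicate 1 (SD over probe sets 0.296) and 0.988 in replicate 2 (SD 0.136), against 0.139 in replicate 3 (SD 0.081). Overall brightness of the array does not account for it, since the hybridization controls, added after labelling, differed by only 0.040 and 0.332 there, and the lower of the 2 remainders was 0.656. Less sample RNA per spike-in as a property of 3D culture was set to require a clear remainder on every 3D array. The remainders of 0.788 and 0.656 in replicates 1 and 2 go with it, and that of -0.066 in replicate 3 goes against it. The condition was therefore not met, but this rests on a single array and does not settle the question. A different amount of spike-in in those 2 preparations also stays open and was not tested.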

How the results depend on the processing

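The test of all 6 arrays without a block was the planned design and became an alternative once the scales were seen. Chosen after the data were seen were the tests with the scale as a block, and with the scale as a block and array weights, and the count of calls that share the sign of replicate 1. On the 4 arrays, quantile normalization, median centring, cyclic loess, trend and robust priors and array weights gave 2433 to 3225 probe sets, 922 to 1260 genes, 289 to 314 genes of at least 2-fold and 6 to 7 lists (G1/S was lost with cyclic loess). Without dim probe sets the counts were 3011, 1242, 282 and 4 lists (apical membrane, G1/S and G2/M were lost), with fewer genes tested. A threshold of 0.01 left 233 probe sets and 93 genes, and treat left 713 and 282. The mean of a gene's probe sets gave 1153 genes, 565 higher and 588 lower, lost the apical membrane list and gained TGF-beta and BMP, and ended the calls of RPH3AL, FN1, PARD3, CD164, PERP, DAG1, ITGB5, ITGB6 and PFKFB3 (limma adjusted p 0.0598 to 0.387); RAB3D missed with median centring (0.0515) and with trend and robust (0.0571), and PRKCI (0.0561) and CRIM1 (0.0506) with the latter. The replicate block left 0 probe sets, 0 genes and 0 genes of at least 2-fold (8325 probe sets at an unadjusted p under 0.05) and 6 lists, without the apical membrane list, but deviations of same-numbered arrays correlated at 0.00127 across probe sets and no label ties the numbers to a shared day. Leaving out 1 array, which assumes that the lone array varies like the pair, gave 0 to 0 calls in all 3 counts and 2 to 5 lists, the lowest without 3D replicate 3. On simulated data a fit without 1 array recovered 87.9% of 2837 probe sets changed by 1 and the blocked fit 95.3%. Of the 2837 probe sets called on the real data, 755 changed by at least 2-fold, so the simulated changes were larger than most real ones. The simulation therefore cannot tell whether lost power explains the lost calls, and their cause was not tested. With all 6 arrays the counts of probe sets, genes and genes of at least 2-fold were 0, 0 and 0 without a block (11 lists) and with the replicate block (2723 probe sets at an unadjusted p under 0.05), 57, 25 and 25 with the number as a random block, 4, 2 and 2 with the scale as a block, 2, 1 and 1 with quantile normalization and with median centring, and 3, 1 and 1 with cyclic loess, where every call under a rescaling was higher. The 25 genes of the random block were all among the 1102. Lists called on all 6 arrays numbered 11 without a block, 8 with the replicate block and 8 with the scale as a block. They numbered 10 with quantile normalization, 9 with median centring and 10 with cyclic loess. Without a block 6 lists were gained and 2 lost against the 4 arrays. Scale as a block with array weights gave 6728 probe sets, 2590 genes, 268 genes of at least 2-fold and 4 lists, and shared 1101 genes with the 1102. Camera with an estimated correlation called 0 lists (1 at an unadjusted p under 0.05) and fry 1 list, the YAP and TAZ targets. The estimated correlations of the YAP and TAZ, apical membrane and G1/S lists (-0.0325, -0.0085 and 0.00885) lay below the preset 0.01. Correlation between members therefore does not account for the calls lost in these lists. With an estimated correlation camera also uses the 2 residual degrees of freedom of the 4 arrays, where the preset uses the number of genes. The settings thus differ in more than the correlation. How much each part weighs in the other lists was not tested. A random block on the 4 arrays could not be estimated and was not run, camera takes no random block, and leaving out a replicate 1 array changes nothing in a test that lacks it. The values carry no background measure, so what signal over background limits is unknown.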

Other observations

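The tests of the replicate 1 scale and the splits of the arrays were chosen after the results were seen, and the 3 gene lists below were written after the report's genes had been seen and before their own results. Genes that build ribosomes in the nucleolus were lower in 3D as a group. Of 26 measured members 8 fell and 0 rose, with a median log2 fold change of -0.378 and a replicate 1 median of -0.52. WDR12 (-1.01, SE 0.124), UTP15 (-0.97, SE 0.102) and DKC1 (-0.94, SE 0.112), which act in ribosomal subunit assembly and RNA modification, fell most, and NOP56 (-0.66) and NOP2 (-0.57) fell as well. The hypothesis was a fall together with MYC, a known activator of these genes, but MYC itself did not enter the test. The list gave a limma camera adjusted p = 3.93e-10 over the 3 lists, and an adjusted p = 0.0877 with an estimated correlation. All 8 also had lower values in 3D in replicate 1, from -0.37 for WDR43 to -1.02 for NOP2. The fall of the list was thus called at the preset correlation and not in the setting with an estimated one. That setting also rests on only 2 residual degrees of freedom, so the lost call does not show that correlation between members undoes the fall. Whether MYC brings the fall about was not tested. The ribosomal proteins themselves had a median of 0.03.

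Genes of motile cilia were tested beside those of the primary cilium. Of 36 measured axoneme and motile cilium genes 2 rose, DRC1 (0.93, SE 0.159) and the transcription factor gene RFX3 (0.61, SE 0.129), and the list gave a limma camera adjusted p = 0.188, so a joint rise of motile cilia genes was not detected; the difference between the 2 lists was not tested. FABP1 is a known target of the liver and kidney factors HNF1 and HNF4. Of 24 measured targets that leave out the genes named in the report, 0 passed, with a limma camera adjusted p = 0.789 and a median of -0.01. The list holds many liver genes, such as ALB, APOA1 and FGB, and leaves out FABP1 itself. It therefore cannot decide whether these factors act in the kidney cells used here.

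The loss of calls when all 6 arrays are fitted together may come from another summary method for the replicate 1 columns, as 100.0% of their values below 1 lay on log2 of multiples of 0.1. An absent response in replicate 1 is argued against by the slope of its differences on the log2 fold changes of replicates 2 and 3, which was 0.836 across the 1102 called genes. At an unadjusted p under 0.05 without a block, 5 of the 10 splits of the 6 arrays into 3 and 3, the real one included, gave at least as many probe sets, with 105 in the real split and 8873 in the highest other. The other 4 were the splits that put both replicate 1 arrays in the same group, which points to a structure of the arrays. The 10 splits are too few for a share under 0.05.

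On replicates 2 and 3 a shift that depends on brightness does not account for the lower YAP and TAZ targets in 3D. There 0 of 10000 random lists matched on level had a median as low, and 9 of the 36 lists were among the 250 lowest or highest of theirs. The count was also 0 in replicate 1, but there 14 of the 36 lists were among the 250 lowest or highest. Of these 14, 10 were not called by camera. The replicate 1 count therefore cannot decide on brightness in that replicate. RNA quality stays open: 2 of the 4 actin and GAPDH control pairs had a larger 3' minus 5' difference on both 3D arrays, where chance gives 0.667. The bound of under 3 pairs set beforehand was thus too wide to exclude it. The means of these pairs were 0.18 in 2D and 0.355 in 3D (GAPDH), and -0.045 and 0.21 (actin). The remaining actin pair had 0.80 and 0.665, the remaining GAPDH pair 0.135 and 0.14. In replicate 1, on its own scale, the actin pairs had 2.17 in 2D and 2.90 in 3D, and -0.29 and -0.08. The GAPDH pairs had 1.67 and 1.47, and 0.52 and 0.50, there. Of the 3 splits of the 4 arrays into 2 and 2, 1 gave as many probe sets, the real one with 2837 against 0 in the highest other, and 3 splits are too few for a share under 0.05. The culture condition itself also stays open and was not tested apart from RNA quality.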
